A study of Mus musculus with 8 samples.

How the data were processed

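RNA was profiled in 8 libraries of beta cells sorted from NOD mice, an inbred strain that develops autoimmune diabetes, at 8 to 10 weeks of age. The labels name 2 sorted populations, top and bottom, with 4 libraries each, and place 2 libraries of each population in batch 1 and 2 in batch 2. Per the labels' protocols, cDNA was made and amplified from about 1000 cells per library with the SMARTer Ultra Low RNA kit, which works on small amounts of RNA, and sequencing libraries were prepared by Nextera XT tagmentation. Replicates 1 and 2 of each population belong to batch 1 and replicates 3 and 4 to batch 2, and apart from that the replicate number only names a library. Nothing in the labels says that the libraries came from separate animals, so p-values measure the spread between these libraries, which may be partly technical.

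The deposited values were expected counts, which are estimates of the reads per gene that RSEM makes by dividing reads that match several genes among them. RSEM, edgeR and the mouse genome build mm9 are named in the submitters' processing notes, and the aligner, the gene annotation and the versions were not given in the sources used here. The deposited expected counts came as 1 table per library and 1 table of the whole series, and the largest difference between them was 0 over 23366 genes. Of all values, 34.8% were not whole numbers, and all were rounded to whole numbers before testing. Genes were identified by the symbols in the deposited tables, which carry no coordinates, so none are given, and a reference of another build was not used here. Because RSEM divides shared reads, the separate levels of Ins1 and Ins2, and of closely related H2 genes, are less certain than their sums. The kit does not keep the strand of the RNA as far as the labels say, so reads of a gene and of an overlapping antisense gene could not be separated. No mitochondrially encoded genes were found by name in the tables, so the share of mitochondrial reads was not measured.

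The following choices were made before the data were examined: the groups, the main test with its covariates, all alternatives except the 3 named as later ones, the gene lists of beta cell biology and of marker genes, and the rule for naming genes. Genes were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Library sizes were scaled by TMM, genes with too few counts were left out by filterByExpr with the population as the grouping, and 11721 genes were tested, which held at least 98.01% of the counts of each library. The edgeR quasi-likelihood test compared bottom with top in an additive model with the batch as a covariate. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. A positive log2 fold change means a higher level in bottom, and its standard error (SE) comes from the same edgeR fit. Levels are in CPM after TMM scaling, given as means of 4 libraries with the standard deviation (SD). The common biological coefficient of variation was 0.806. A test of the interaction between batch and population used the same counts. Intervals on count ratios are exact binomial intervals at 95% confidence, and the floor for a count of 0 was 3 counts over the population. Both cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

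Shares of counts and numbers of detected genes were compared by two-sided exact permutation tests of the difference of means over all 70 relabellings of the 8 libraries, whose smallest possible p is 0.0286. Relabelling within batches leaves 36 arrangements and a smallest possible p of 0.0556. The p-values of 6 hormone shares were adjusted together by the Benjamini-Hochberg method.

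Gene lists were tested with camera from limma, two-sided, with a preset correlation of 0.01 between genes, in the same design as the gene test, and adjusted over the 29 lists with at least 3 tested genes. The 21 lists of beta cell biology covered beta cell identity, beta cell autoantigens, secretory granules and exocytosis, endocrine progenitors and dedifferentiation, genes disallowed in beta cells, the cell cycle, cyclins and cell cycle inhibitors, MHC class I, nonclassical MHC class I, MHC class II, the interferon response, chemokines with cytokines and NF-kappaB targets, immune inhibitory ligands and enzymes, the unfolded protein response, apoptosis and survival, glycolysis, oxidative phosphorylation, antioxidant and detoxification genes, ribosomal proteins, immediate early and dissociation stress genes, and markers of beta cell maturation and heterogeneity. The 15 marker lists covered alpha, delta, PP and epsilon, acinar, duct, endothelial, stellate and fibroblast, Schwann and neuronal, pan-leukocyte, T, B, macrophage, dendritic, NK, and erythrocyte and platelet genes. Camera was repeated with the correlation estimated per list, and fry was run, which tests whether the genes of a list move one way on balance and does not compare them with other genes. For each list the number of genes past the threshold is given over all genes tested and adjusted over the list alone. A further 5 lists were written after part of the data had been seen, and serve the tests of explanations in the closing section, while the sums of the intestinal one are also given beside other results.

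Genes were named by a fixed rule. It took the 8 genes with the largest log2 fold change in each direction among those with an adjusted p under 0.05, a mean of at least 10 CPM in the higher population, no overlap between populations and the same direction in both batches, leaving out unnamed gene models. It added the 3 genes with the smallest p of each list of beta cell biology, the 2 genes with the highest mean CPM of each marker list, and always Ins1, Ins2, Pdx1, Mafa, Gcg, Sst, Ppy, Ptprc, Cd274 and Mki67. Not all of these are printed, and some results are not reported here. Ero1lb, Hhex, Ambp, Slc2a2, Ucn3, Fabp2, Apoa1, Sparc, Cdhr2, Cyp2b10, C3 and Timp3 fall outside the rule and were chosen after their values were seen.

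The alternatives were RLE and upper-quartile scaling, TMM computed without the genes that each take over 1% of a library, no low-count filter, a filter of 5 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, limma-trend on the log2 scale of the series table with a prior count of 2, no batch term, each batch alone, a block made of the batch and the number in the library title, and the omission of each library in turn. For the list test they were an estimated correlation and fry, for the shares and detected genes relabelling within batches, a denominator without ribosomal protein genes, detection at 5 counts and thinning. A further 3 alternatives were chosen after seeing the data: thinning every library to the smallest total, a robust quasi-likelihood prior, and the omission of bottom 1 and top 3 together. All 35 splits of the 8 libraries into 4 and 4 were also tested.

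The library titles carry a number within each batch, and only number 1 is shared by top and bottom, so the numbers were not taken to pair libraries. Deviations from the population means correlated at 0.07 on average across genes for libraries of the same batch and the other population, and at -0.071 for libraries of the other batch. Libraries of the same population and batch differed by far more than counting noise, with a chi-square per degree of freedom of 41 to 233.3, so none was a second deposit of another.

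The gene test was run on simulated counts for 11334 genes, made from the means and library sizes of the bottom and top libraries with a known set of changed genes. It called 67 genes, of which 3 had not been changed. It recovered 76.9% of 65 genes changed by a log2 fold change of 4, 21.2% of 66 changed by 2 and 0% of 66 changed by 1, so the absence of a call does not show the absence of a small change. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.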

Results

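The series holds RNA profiles of beta cells, the insulin-producing cells of the pancreatic islets, sorted from NOD mice into a top and a bottom population. Each population had 4 libraries, 2 in batch 1 and 2 in batch 2. Total estimated counts were 7811383, 9366913, 9276276 and 6657639 in top 1 to top 4. They were 9348428, 11262368, 7256042 and 8755683 in bottom 1 to bottom 4 (exact permutation p = 0.486 for the difference of means). At least 1 count was seen for 13460 ± 649 genes in top and 13910 ± 366 genes in bottom (SD, n = 4, exact permutation p = 0.286). The design asks how the transcriptome of the bottom beta cells differs from that of the top beta cells.

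The populations differed first in their hormone transcripts. Insulin, from Ins1 and Ins2 together, made up 33.5% ± 5.92 of the counts in top libraries and 5.34% ± 1.99 in bottom libraries (SD, n = 4). Somatostatin (Sst), the hormone of delta cells, made up 0.282% ± 0.106 in top and 4.59% ± 0.654 in bottom. Pancreatic polypeptide (Ppy), the hormone of PP cells, made up 0.105% ± 0.0585 in top and 4.28% ± 3.11 in bottom. The related peptide YY (Pyy) made up 0.0719% ± 0.0112 in top and 0.842% ± 0.445 in bottom. For these 4 shares the populations did not overlap, and each exact permutation test gave p = 0.0286, the smallest it can give, or 0.0429 after adjustment over 6 hormone shares. Insulin differed by -33.6 percentage points in batch 1 and -22.8 in batch 2, somatostatin by 4.91 and 3.71, Ppy by 6.80 and 1.56, and Pyy by 1.16 and 0.383. Relabelling within batches gave p = 0.0556 for each, the smallest that this exact test allows. Glucagon (Gcg), the hormone of alpha cells, made up 7.89% ± 2.88 in top and 6.66% ± 4.31 in bottom (SD, n = 4, exact permutation p = 0.571). It was 3.18 percentage points higher in bottom in batch 1, and its difference in batch 2 was -5.63. The batch 1 rise rests on bottom 2, at 13.1%, since bottom 1, at 4.83%, lay below top 1 and top 2, at 6.24% and 5.29%. Amylin (Iapp), which beta cells secrete with insulin, made up 2.84% ± 0.299 in top and 1.90% ± 1.09 in bottom (SD, n = 4, exact permutation p = 0.257). Its difference was -1.61 percentage points in batch 1 and -0.267 in batch 2. The 100 most abundant genes of each library took 57.5% ± 1.89 of the counts in top and 42.8% ± 5.54 in bottom (SD, n = 4, exact permutation p = 0.0286). Without top 1, top 2, top 3 or top 4 the exact p of that last difference was 0.0571, and the difference was -14.6, -13.9, -15.1 and -15.4 percentage points.

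**Figure D1:**
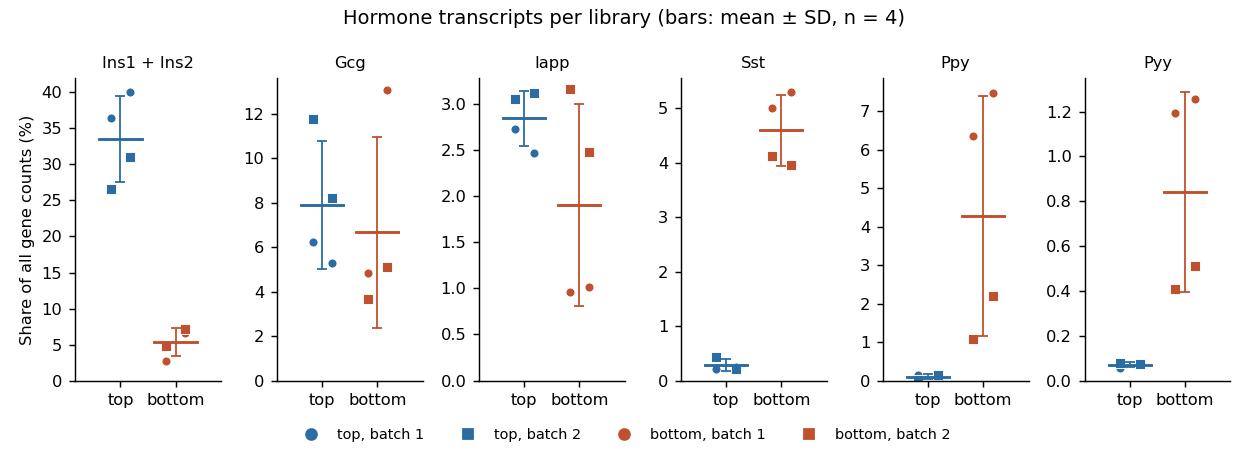
Each panel shows the share of all gene counts (%, linear vertical axis from 0) taken by a hormone's transcripts in each library of top and bottom cells, with circles for batch 1, squares for batch 2, and bars for the mean ± SD of 4 libraries. Insulin lies between 26.6% and 40.1% in top and between 2.75% and 7.16% in bottom, and somatostatin between 0.22% and 0.44% in top and between 3.95% and 5.29% in bottom.

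Across the transcriptome, 33 genes were higher and 19 lower in bottom among 11721 tested, and each of these 52 differed by at least 2-fold (edgeR quasi-likelihood test, adjusted p under 0.05). Among the largest rises were Ccl19, a chemokine that attracts cells bearing CCR7, the LIM-domain gene Lmo3, and the extracellular matrix genes Col3a1 and Dcn. Among the largest falls were Gad1, which makes the neurotransmitter GABA, and Pcx, the pyruvate carboxylase that feeds the citric acid cycle. All 52 genes had the same direction in both batches. For 50 of them, all but Dnajb1 and the cadherin family gene Cdhr2, the libraries of the populations did not overlap, as for 844 of all tested genes (7.2%, where chance gives 2.86%). The count of 52 became 12 without top 1, 8 without top 2, 28 without top 3, 14 without top 4, 33 without bottom 2, 23 without bottom 3 and 11 without bottom 4. DESeq2 called 587 genes and limma-trend 137, and edgeR 204 without the low-count filter, 32 without the batch term and 2 in each batch alone. With a block made of the batch and the numbers in the library titles edgeR called 0. In that fit only the libraries numbered 1 compare the populations within a block, so the 0 is not comparable with the other counts. Of 34 called genes named in the text, Ins1, Ins2, G6pc2, Sytl4, Sst and Cd24a stayed past the threshold in every omission, and the numbers lost were 25, 28, 18 and 24 without top 1 to top 4 and 9, 17, 17 and 25 without bottom 1 to bottom 4.

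**Figure D2:**
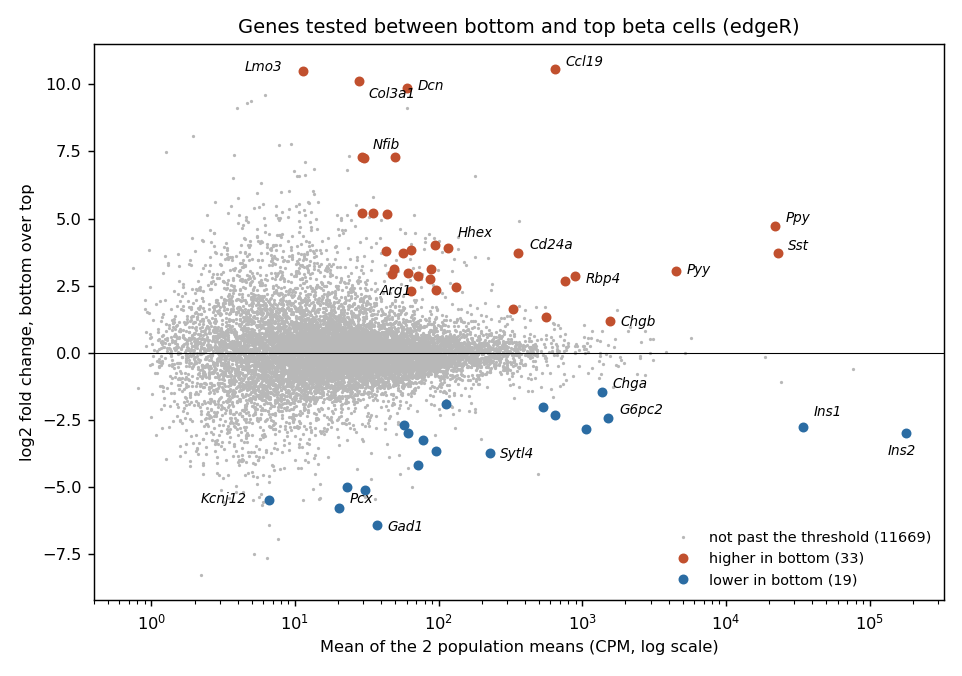
Each point is a gene, with the mean of its 2 population means on the horizontal axis (CPM, log scale) and its edgeR log2 fold change, bottom over top, on the vertical axis. The 33 genes higher in bottom and the 19 lower in bottom are coloured, all other tested genes are grey, and Ins2 and Sst lie on opposite sides at -2.99 and 3.71.

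Genes of beta cell identity were lower in bottom. Ins2 averaged 318160 CPM in top and 39454 in bottom, a log2 fold change of -2.99 (SE 0.30, n = 4, edgeR adjusted p = 0.00498). Ins1 averaged 60270 and 8718 CPM, a log2 fold change of -2.76 (SE 0.27, edgeR adjusted p = 0.00498). G6pc2, the islet-specific glucose-6-phosphatase subunit, was 5.32-fold higher in top, at 2551 against 478 CPM (edgeR adjusted p = 0.00498). Ero1lb, an oxidase of the endoplasmic reticulum that helps proinsulin to fold, was 7.10-fold higher in top, at 1836 against 291 CPM (edgeR adjusted p = 0.0305). These 4 genes fell among the 24 tested genes of the list and none rose, while 11 fell and 1 rose with p adjusted over the list alone. The list had a median log2 fold change of -1.0, and camera called it lower with the preset correlation (adjusted p = 1.94e-13) and with an estimated one (adjusted p = 0.0326). The glucose transporter Slc2a2 stood at 345 CPM in top and 48.1 in bottom (log2 fold change -3.20, SE 0.56, edgeR adjusted p = 0.0503). Ucn3, a marker of mature beta cells, stood at 933 and 49.6 CPM (log2 fold change -4.51, SE 0.81, edgeR adjusted p = 0.0589). Pdx1, a transcription factor of beta cells, stood at 4.84 and 3.97 CPM (edgeR adjusted p = 0.950). Mafa, another such factor, had 0 counts in all 8 libraries, so its level was not detectable here in either population. Ero1lb was no longer called without top 1, top 2, top 4, bottom 2 or bottom 3 (edgeR adjusted p up to 0.121). Slc2a2 passed without bottom 1 (edgeR adjusted p = 0.00597, and 0.00597 to 0.188 over all omissions) and Ucn3 without bottom 1 or bottom 2 (0.0166 to 0.182 over all omissions), while the sign of Pdx1 turned without top 4 (log2 fold change 0.35). The bottom mean was 25.5 CPM for Slc2a2 without bottom 1 and 15.8 CPM for Ucn3 without bottom 2.

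Genes whose proteins are targets of the autoimmune response were lower in bottom as a list. Gad1 averaged 73.6 ± 9.68 CPM in top and 0.849 ± 0.792 in bottom, a log2 fold change of -6.42 (SE 0.80, n = 4, edgeR adjusted p = 0.0139). Its bottom mean was 0.508 CPM without bottom 2. Chga, the granule protein chromogranin A and a source of T cell epitopes in NOD mice, was 2.72-fold higher in top, at 1994 against 737 CPM (edgeR adjusted p = 0.0493). With Ins1, Ins2 and G6pc2, which the identity list holds too, 5 of 16 genes fell and none rose, and 7 fell with p adjusted over the list alone. The median log2 fold change was -0.71, and camera called the list lower with the preset correlation (adjusted p = 7.98e-09) and with an estimated one (adjusted p = 0.0447). Gad1 was no longer called without top 1, top 2, top 4 or bottom 4 (edgeR adjusted p up to 0.0711), and Chga without any 1 of top 1 to top 4, bottom 3 or bottom 4 (up to 0.182).

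In the secretory granule and exocytosis list, genes moved both ways. Sytl4, the granuphilin that docks insulin granules, fell from 418 ± 82.9 CPM in top to 34.0 ± 15.8 in bottom (log2 fold change -3.72, SE 0.35, n = 4, edgeR adjusted p = 0.00498), and Chga fell as given. Chgb, the granule protein chromogranin B, rose from 942 to 2156 CPM (log2 fold change 1.19, SE 0.20, edgeR adjusted p = 0.0491). Thus 1 gene rose and 2 fell among 31 tested, and 2 rose and 6 fell with p adjusted over the list alone. The median log2 fold change was -0.28, and camera called the list lower with the preset correlation (adjusted p = 0.000521). Its adjusted p was 0.281 with an estimated correlation, and Chgb was no longer called in any omission except that of top 3, so without top 1, top 2, top 4 or any 1 of bottom 1 to bottom 4 (edgeR adjusted p up to 0.184).

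Other falls lay outside the lists. The pyruvate carboxylase Pcx stood at 39.6 CPM in top and 0.786 in bottom (log2 fold change -5.78, SE 0.94), and the potassium channel Kcnj12 at 13.0 and 0.252 CPM (-5.47, SE 0.93). Mns1, a gene of cilia and sperm flagella, stood at 59.2 and 2.64 CPM (-5.10, SE 0.80), and T2 at 44.6 and 1.53 CPM (-4.99, SE 0.80). The organic anion transporter Slco1a6 fell from 135 to 8.63 CPM (-4.19, SE 0.57), and the carbonic anhydrase Car15 from 177 to 14.6 CPM (-3.64, SE 0.40). Adjusted p in edgeR lay between 0.00623 and 0.0462 for these 6 genes. The bottom mean without bottom 4 was 0.399 CPM for Pcx and 0.751 CPM for T2. Without top 2 none of the 6 was called, Car15 was also lost without bottom 4, and the others were lost in 6 to 8 of the omissions (edgeR adjusted p up to 0.168, for Kcnj12).

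Markers of delta and PP cells were higher in bottom, while no marker of alpha cells passed the test. Sst rose 13.1-fold, from 3187 ± 1263 CPM in top to 42608 ± 12605 in bottom (log2 fold change 3.71, SE 0.33, n = 4, edgeR adjusted p = 0.00498). Rbp4, a retinol carrier, rose 7.31-fold, from 220 to 1564 CPM (edgeR adjusted p = 0.00498), and Hhex, a transcription factor of delta cells, 15.1-fold, from 13.2 to 220 CPM (edgeR adjusted p = 0.0275). These were 3 of the 5 tested genes of the delta cell list, and 4 rose with p adjusted over the list alone. Camera called that list higher with the preset correlation (adjusted p = 1.34e-13) and with an estimated one (adjusted p = 0.015). Both tested genes of the PP and epsilon cell list rose, over all genes and adjusted over the list alone. Ppy rose 26.7-fold (log2 fold change 4.74, SE 0.64, edgeR adjusted p = 0.0203) and Pyy 8.38-fold (3.07, SE 0.40, edgeR adjusted p = 0.0187). None of the 9 tested alpha cell genes changed over all genes or adjusted over the list alone. Their median log2 fold change was -0.41, and camera made no call (adjusted p = 0.36). Gcg had a log2 fold change of -0.59 (SE 0.49, edgeR adjusted p = 0.784), and Ttr, a thyroid hormone carrier abundant in alpha cells, one of -0.82 (SE 0.43, edgeR adjusted p = 0.582). Calls were lost for Ppy without top 1, top 2 or bottom 4 (edgeR adjusted p up to 0.118), for Pyy without top 1, top 2, top 4 or bottom 4 (up to 0.113), for Rbp4 without top 2 (0.0505), and for Hhex without top 1 to top 4, bottom 2 or bottom 4 (up to 0.132). The bottom mean of Hhex was 135 CPM without bottom 3. Without bottom 2, camera called the alpha cell list lower (adjusted p = 0.0413, and 0.0413 to 0.483 over all omissions), as it did in batch 2 alone (0.0244) but not in batch 1 alone (0.745).

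Among markers of beta cell maturation and heterogeneity, Cd24a, a glycoprotein of the cell surface, rose 13.3-fold. It averaged 52.4 ± 23.4 CPM in top and 666 ± 239 in bottom, with the smallest adjusted p of all tested genes (log2 fold change 3.74, SE 0.30, n = 4, edgeR adjusted p = 0.00378). With Rbp4 and Pyy, which the delta cell and PP cell lists hold too, 3 of 16 genes rose and none fell, and 6 rose and 3 fell with p adjusted over the list alone. The median log2 fold change was 0.83, and camera called the list higher with the preset correlation (adjusted p = 0.00225), but the adjusted p was 0.112 with an estimated correlation. Without bottom 2 the call was lost with the preset one too (adjusted p = 0.0923, and 0.00173 to 0.0923 over all omissions).

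Genes of endocrine progenitors and of beta cell dedifferentiation were higher in bottom as a list, although no member passed the threshold over all genes. Of 15 tested genes 14 had a positive log2 fold change, the median was 1.92, and 2 rose with p adjusted over the list alone. Vim, the intermediate filament vimentin, had 4 counts in top and 972 in bottom (edgeR adjusted p = 0.0879, and 0.0352 without bottom 1, with 0.0352 to 0.26 over all omissions). Camera called the list higher with the preset correlation (adjusted p = 2.11e-06) and with an estimated one (adjusted p = 0.0305). Genes disallowed in beta cells, which most tissues express and mature beta cells keep silent, had a median log2 fold change of 3.37, and 14 of 15 were positive. Nfib, a transcription factor, rose from 0.521 to 57.7 CPM (log2 fold change 7.31, SE 0.94, edgeR adjusted p = 0.0162). Acot7, an acyl-CoA thioesterase, rose from 2.21 to 85.5 CPM (5.17, SE 0.85, edgeR adjusted p = 0.0452). These 2 genes rose over all genes and 9 adjusted over the list alone. Camera called this list with the preset correlation (adjusted p = 4.85e-14) and with an estimated one (adjusted p = 0.0326). The monocarboxylate transporter Slc16a1 stood at 0.883 and 20.4 CPM (edgeR adjusted p = 0.0692), and the lactate dehydrogenase Ldha at 14.8 and 286 CPM (edgeR adjusted p = 0.254). Ldha stood at 834, 239, 26.7 and 43.7 CPM in bottom 1 to bottom 4, beside summed intestinal transcripts of 26310, 6137, 125 and 188 CPM, and its bottom mean was 103 CPM without bottom 1. The summed fibroblast and stellate cell genes stood at 3.5, 275, 332 and 1470 CPM in bottom 1 to bottom 4 and at 1.45 to 16.2 CPM in top. The bottom mean of Nfib was 33 CPM without bottom 4, and the top mean of Acot7 1.46 CPM without top 3. Top means were also 0.166 CPM for Nfib without top 4 and 6.68 CPM for Ldha without top 1. Nfib was no longer called without top 1, top 2, top 3 or bottom 4 (edgeR adjusted p up to 0.123), and Acot7 without top 1, top 2, top 4, bottom 2, bottom 3 or bottom 4 (up to 0.17).

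**Figure D3:**
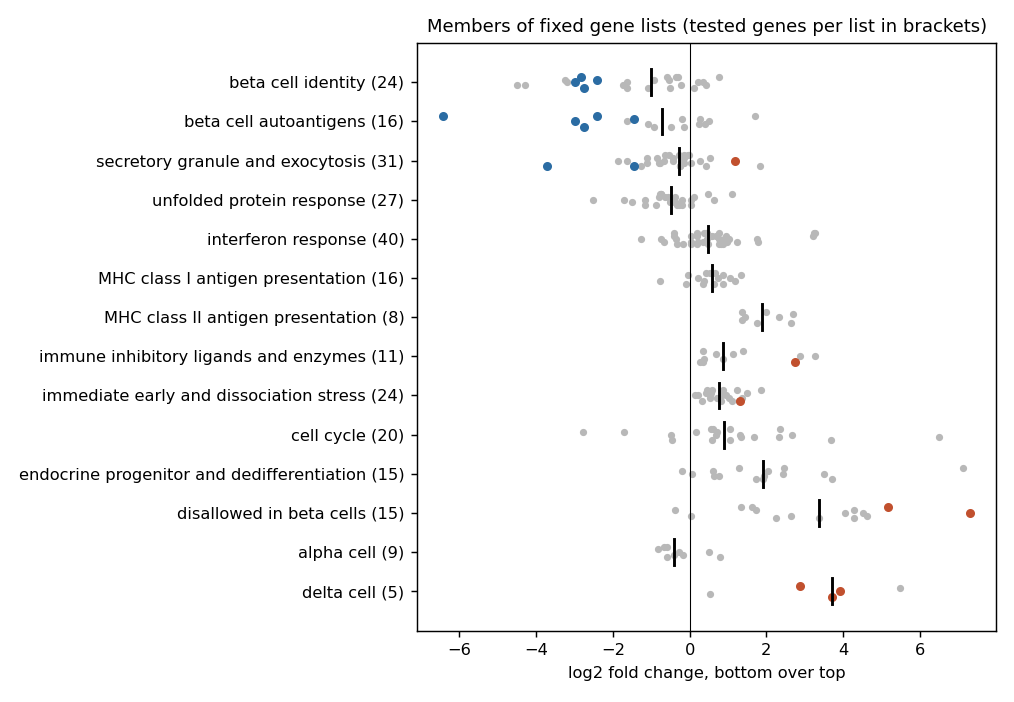
Each point is a tested gene of 1 of 14 fixed lists, placed by its edgeR log2 fold change, bottom over top (horizontal axis), with the number of tested genes in brackets and the list median as a black bar. Coloured points passed an adjusted p of 0.05 over all genes, and the plotted medians include -0.71 for beta cell autoantigens and 3.37 for genes disallowed in beta cells.

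Among immune inhibitory ligands and enzymes, Arg1, the arginase that degrades arginine, rose from 23.5 ± 10.5 CPM in top to 151 ± 17.9 in bottom (log2 fold change 2.75, SE 0.34, n = 4, edgeR adjusted p = 0.0139). It was the 1 gene of 11 that passed, over all genes and adjusted over the list alone, and all 11 had positive values with a median of 0.87. Camera called the list higher with the preset correlation (adjusted p = 5.94e-05) and with an estimated one (adjusted p = 0.0326). Leukocytes express several of these genes too, and summed pan-leukocyte markers stood at 33.7, 12.6, 13.2 and 41.1 CPM in bottom 1 to bottom 4 and at 5.42 to 11.4 CPM in top, beside 133, 147, 148 and 176 CPM of Arg1 in bottom. Cd274, which encodes the checkpoint ligand PD-L1, stood at 82.5 ± 93.8 CPM in top and 85.4 ± 17.4 in bottom (log2 fold change 0.27, SE 0.59, n = 4, edgeR adjusted p = 0.930). Cd47, which restrains phagocytosis, stood at 109 and 172 CPM (0.69, SE 0.26, edgeR adjusted p = 0.382). Arg1 was no longer called without top 1, top 2, top 4 or bottom 4 (edgeR adjusted p up to 0.0899), and the sign of Cd274 turned without top 4 (log2 fold change -0.01). Without top 3 the top mean of Cd274 was 35.7 CPM and its log2 fold change 1.26 (edgeR adjusted p = 0.271).

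MHC class II genes, which present peptides to CD4 T cells, were higher in bottom as a list with the preset correlation. All 8 tested genes had positive log2 fold changes with a median of 1.88. None passed the threshold over all genes, and 3 rose with p adjusted over the list alone. H2-Ab1 stood at 95.8 ± 140 CPM in top and 367 ± 128 in bottom (log2 fold change 2.33, SE 0.76, n = 4, edgeR adjusted p = 0.294), and its partner chain H2-Aa at 206 ± 311 and 518 ± 268 CPM (1.76, SE 0.72, edgeR adjusted p = 0.423). The camera adjusted p of the list was 6.33e-07 with the preset correlation and 0.147 with an estimated correlation. Top 3 held 1776 CPM summed over the list, against 78.5 to 170 CPM in the other top libraries and 882 to 2041 CPM in bottom. Summed pan-leukocyte markers stood at 11.1 CPM in top 3, 5.42 to 11.4 CPM in the other top libraries and 12.6 to 41.1 CPM in bottom. Without top 3, H2-Ab1 (edgeR adjusted p = 0.0275) and H2-Aa (0.0477) passed the threshold, with top means of 25.8 and 50.5 CPM, and over all omissions the values were 0.0275 to 0.604 and 0.0477 to 0.755.

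MHC class I and interferon response genes showed smaller differences. The median log2 fold change was 0.59 over 16 MHC class I genes, 0.77 over 13 nonclassical class I genes and 0.48 over 40 interferon response genes. No gene of these 3 lists changed over all genes or adjusted over the list alone. H2-D1, a classical class I chain, stood at 698 ± 536 CPM in top and 1354 ± 263 in bottom (1.05, SE 0.39, n = 4, edgeR adjusted p = 0.368). Its top mean was 430 CPM without top 3. Summed interferon response genes stood at 9426 CPM in top 3, 1298 to 1858 CPM in the other top libraries and 2074 to 7531 CPM in bottom. Camera called the 3 lists higher with the preset correlation (adjusted p = 0.00491, 0.00353 and 0.00352). Their adjusted p was 0.351, 0.256 and 0.472 with an estimated correlation. Without top 4 the class I call (adjusted p = 0.175) and the interferon call (0.643) were lost, and without bottom 3 the interferon call (0.1). Over all omissions the adjusted p was 3.11e-06 to 0.175 for class I and 4.05e-07 to 0.643 for the interferon list.

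Immediate early and dissociation stress genes were higher in bottom as a list, and all 24 tested members had positive log2 fold changes, with a median of 0.77. Dnajb1, a heat shock cochaperone, rose from 312 ± 134 CPM in top to 807 ± 419 in bottom (log2 fold change 1.32, SE 0.20, n = 4, edgeR adjusted p = 0.0356). It was the 1 gene past the threshold over all genes, and 9 rose with p adjusted over the list alone. Fosb and Klf6, transcription factors induced soon after a stimulus, stood at 479 and 917 CPM (0.94, SE 0.20, edgeR adjusted p = 0.0893) and at 162 and 433 CPM (1.37, SE 0.26, edgeR adjusted p = 0.0680). Camera called the list higher with the preset correlation (adjusted p = 2.56e-09) and with an estimated one (adjusted p = 0.0305). Dnajb1 was no longer called without any 1 of top 1 to top 4 or bottom 2 to bottom 4 (edgeR adjusted p up to 0.149).

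None of the 27 tested genes of the unfolded protein response changed over all genes or adjusted over the list alone, and their median log2 fold change was -0.50. Asns, the asparagine synthetase induced by amino acid shortage, stood at 94.9 CPM in top and 33.6 in bottom (-1.51, SE 0.42, edgeR adjusted p = 0.213). Camera called the list lower with the preset correlation (adjusted p = 0.00185), but the adjusted p was 0.0924 with an estimated correlation. Of 20 tested cell cycle genes none changed over all genes, and 1 rose with p adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, had 2 counts in top and 294 in bottom, a ratio of 107 with a counting interval of 29.4 to 890 (edgeR adjusted p = 0.0939). The proliferation marker Mki67 stood at 3.03 ± 4.88 and 20.1 ± 29.5 CPM (3.69, SE 1.63, n = 4, edgeR adjusted p = 0.482). Its top mean was 0.603 CPM without top 2, and without bottom 2 its bottom mean was 5.62 CPM and its ratio of pooled counts 1.85 instead of 6.59. The cell cycle list had a median of 0.89, and camera called it higher with the preset correlation (adjusted p = 0.0177), but the adjusted p was 0.281 with an estimated correlation. Among 11 cyclins and cell cycle inhibitors, with a median of -0.20, none changed over all genes, 1 fell adjusted over the list alone, and camera made no call (adjusted p = 0.162). The cell cycle call was lost without top 4 (adjusted p = 0.0565) and without bottom 2 (0.313), while the cyclin list was called without top 4 (0.0395). Over all omissions the adjusted p was 0.00302 to 0.313 and 0.0395 to 0.423.

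The remaining lists of beta cell biology held no gene past the threshold over all genes. Chemokines, cytokines and NF-kappaB targets had a median log2 fold change of 0.93 over 16 genes, and 6 rose with p adjusted over the list alone. Cxcl16, a chemokine that also occurs as a membrane protein, stood at 1.81 and 40.9 CPM (4.57, SE 1.12, edgeR adjusted p = 0.154). Its top mean was 0.876 CPM without top 1. Apoptosis and survival genes had a median of 0.84 over 22 genes, none of which passed adjusted over the list alone. Camera called both lists higher with the preset correlation (adjusted p = 0.000153 for each), but the adjusted p was 0.0879 for each with an estimated correlation. Antioxidant and detoxification genes had a median of 0.45 over 22 genes, with 2 higher and 2 lower adjusted over the list alone. Oxidative phosphorylation genes had a median of 0.28 over 48 genes, with none past the threshold adjusted over the list alone. Camera called these 2 lists higher with the preset correlation (adjusted p = 0.00647 and 0.0253), but the adjusted p was 0.302 and 0.656 with an estimated correlation. Glycolysis genes had a median of 0.22 over 20 genes and ribosomal protein genes one of 0.11 over 77, with none past the threshold adjusted over the list alone and no camera call (adjusted p = 0.124 and 0.0834). Without top 1, top 2 or bottom 1 the antioxidant call was lost (adjusted p = 0.0558, 0.0867 and 0.108), as was that of oxidative phosphorylation (0.477, 0.203 and 0.731), which turned lower without bottom 1. In batch 1 alone camera called oxidative phosphorylation (adjusted p = 1.41e-05) and antioxidant genes (8.03e-05) higher, and in batch 2 alone it called oxidative phosphorylation lower (0.0448), with antioxidant genes on the lower side (0.544). The bottom libraries of batch 1 are those with the most acinar and intestinal transcripts, whose sums are given below. The ribosomal list was called higher without top 2 (adjusted p = 0.0264, and 0.0264 to 0.674 over all omissions), with RLE scaling (0.038), with the filter of 5 CPM (0.0331), in DESeq2 (0.0477) and in limma-voom (0.00259). The glycolysis list was called higher in batch 1 alone (0.0256) and lay on the lower side in batch 2 alone (0.942).

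Markers of fibroblasts and stellate cells were higher in bottom. Col3a1, a collagen gene, had 1 count in top and 2397 in bottom, a ratio of 1750 with a counting interval of 314 to 69100 (edgeR adjusted p = 0.0462). Dcn, a proteoglycan gene, had 2 and 5028 counts, a ratio of 1840 with an interval of 508 to 15200 (edgeR adjusted p = 0.0356). In bottom 1 to bottom 4 Col3a1 stood at 1.20, 25.9, 9.69 and 187 CPM and Dcn at 1.86, 26.6, 104 and 346 CPM, and without bottom 4 the ratios were 379 and 645. These 2 of 5 tested genes rose, and 4 rose with p adjusted over the list alone. The median log2 fold change was 5.81, that of Col1a2, which stood at 0.109 to 130 CPM in bottom and 0 to 12.2 CPM in top. It was the same with Col3a1 and Dcn held at a floor of 3 counts over the top population. Both genes stay above the median at that floor, so this could not move it. Camera called the list higher with the preset correlation (adjusted p = 4.91e-07), but the adjusted p was 0.0987 with an estimated correlation. Ccl19 stood at 0.740 ± 0.183 CPM in top and at 16.8, 1380, 188 and 3560 CPM in bottom 1 to bottom 4. It had 22 counts in top and 55122 in bottom, a ratio of 1830 with an interval of 1210 to 2920, or 758 without bottom 4 (edgeR adjusted p = 0.0367). Lmo3 had 0 counts in top and 890 in bottom, at least 217-fold higher at the same floor, or 139-fold without bottom 1 (edgeR adjusted p = 0.0462). Slc7a7, a transporter of cationic amino acids, rose from 0.648 to 98.1 CPM (log2 fold change 7.31), and Zfp36l1, which speeds the decay of mRNA, from 0.489 to 59.8 CPM (7.24). Slc4a4, a sodium bicarbonate transporter, rose from 1.59 to 56.8 CPM (5.23), and edgeR adjusted p lay between 0.0249 and 0.0462 for the last 3 genes. Without top 1 the top mean was 0.0419 CPM for Slc7a7 and 0.892 CPM for Slc4a4, and without top 2 it was 0.192 CPM for Zfp36l1. Slc7a7 stood at 312, 71.7, 3.43 and 4.77 CPM in bottom 1 to bottom 4, highest in the 2 libraries with the most intestinal and acinar transcripts, and its bottom mean was 26.6 CPM without bottom 1. None of these 7 genes was called without top 2, top 3, top 4 or bottom 4, each was lost in at least 2 of the omissions of top 1, bottom 1, bottom 2 and bottom 3 too, and Lmo3 in all 8 omissions (edgeR adjusted p up to 0.215, for Col3a1).

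Some duct and acinar cell genes were higher in bottom. The keratin gene Krt8 rose from 159 CPM in top to 502 ± 147 in bottom (log2 fold change 1.64, SE 0.27, n = 4, edgeR adjusted p = 0.0462). Ambp, which encodes the precursor of alpha-1-microglobulin and bikunin, rose from 15.8 to 127 CPM (2.85, SE 0.50, edgeR adjusted p = 0.0497). These were 2 of 11 tested duct genes, and 4 rose with p adjusted over the list alone. Of 21 tested acinar genes 1 rose over all genes, and 2 rose with p adjusted over the list alone. Summed acinar transcripts stood at 16710, 5592, 554 and 398 CPM in bottom 1 to bottom 4 and at 146 to 911 CPM in top. Summed intestinal transcripts, from a list written after part of the data had been seen, stood at 26310, 6137, 125 and 188 CPM in bottom 1 to bottom 4 and at 63.9 to 1674 CPM in top. The median log2 fold change was 1.26 for the duct list and 2.42 for the acinar list, and camera called both higher with the preset correlation (adjusted p = 1.91e-05 and 4.91e-07). Their adjusted p was 0.0979 and 0.245 with an estimated correlation. Ambp was lost in all 8 omissions and Krt8 in all but that of bottom 1 (edgeR adjusted p up to 0.188, for Krt8).

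Leukocyte transcripts were few in both populations. Ptprc, which encodes the pan-leukocyte antigen CD45, had 9 counts in top and 34 in bottom, a ratio of 2.76 with a counting interval of 1.30 to 6.54, and was too low to be tested. Without bottom 3 the ratio was 0.637. Rac2, a GTPase of blood cells and the 1 tested gene of the pan-leukocyte list, stood at 3.46 ± 1.28 and 8.46 ± 8.51 CPM (1.16, SE 0.93, n = 4, edgeR adjusted p = 0.773), and did not pass adjusted over the list alone either. Its bottom mean was 4.26 CPM without bottom 1. The T cell list had 3 tested genes with a median of 1.69, and none changed over all genes or adjusted over the list alone. Camera made no call (adjusted p = 0.0607), although fry called the list higher (adjusted p = 0.00663), and camera called it higher without top 1, top 2, top 3, top 4, bottom 1 or bottom 2 (adjusted p = 0.000411, 0.0013, 0.00443, 0.00877, 0.00983 and 0.000112), in batch 2 alone (7.77e-05) and in limma-trend (0.0146). Summed T cell genes stood at 5.43 to 10.8 CPM in top and 15.9 to 159 CPM in bottom. Of 5 tested dendritic cell genes, 3 are MHC class II genes, none changed over all genes, and 2 rose adjusted over the list alone. The median was 1.76, and camera called the list higher with the preset correlation (adjusted p = 0.00332), but the adjusted p was 0.245 with an estimated correlation. In the B cell and macrophage lists 2 genes each were tested, with medians of -1.94 and -0.47. None changed over all genes, and 1 B cell gene fell adjusted over the list alone. The 1 tested endothelial gene had a log2 fold change of 1.63 and did not pass over all genes or adjusted over the list alone. No gene of the NK cell list or of the erythrocyte and platelet list could be tested, with sums of at most 3.49 and 6.67 CPM. Of 3 tested Schwann cell and neuron genes none changed over all genes or adjusted over the list alone, and the median of -0.72 was negative while camera placed the list on the higher side (adjusted p = 0.804).

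**Figure D4:**
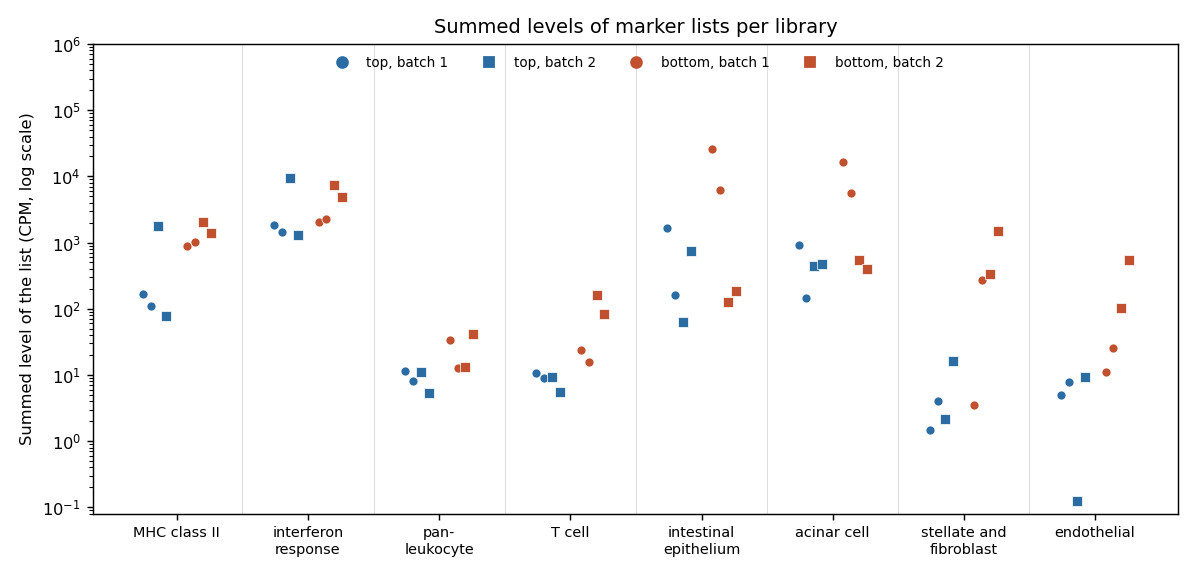
For 8 gene lists, the summed level per library (CPM, vertical axis, log scale) is shown for top and bottom cells, with circles for batch 1 and squares for batch 2. Top 3 stands at 1776 CPM for MHC class II against 78.5 to 170 CPM in the other top libraries, and bottom 1 and bottom 2 stand at 26310 and 6137 CPM for intestinal epithelium against 125 and 188 CPM in bottom 3 and bottom 4.

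Whether the difference between populations depended on the batch was tested as an interaction. No gene passed an adjusted p of 0.05 in edgeR (smallest adjusted p = 0.499), and 885 genes had an unadjusted p under 0.05, where chance gives 586. Without the low-count filter, edgeR called 71 genes, and no other tool was run for this test. Within batch 1 alone, with 2 libraries on each side, Ppy (log2 fold change 5.66) and Sst (4.29) were called, both higher in bottom (edgeR adjusted p = 0.0243). Within batch 2 alone C3, a complement component (10.47, edgeR adjusted p = 0.0118), and Timp3, an inhibitor of matrix proteases (11.31, 0.0215), were called, both higher in bottom. Over both batches C3 stood at 4.38 CPM in top (0.606 without top 2) and 354 in bottom (224 without bottom 4), with a log2 fold change of 6.58 (SE 1.86, edgeR adjusted p = 0.222), and Timp3, with 4 and 4357 counts, was too rarely seen to be tested. Averaged over populations, Cyp2b10, a cytochrome P450, differed between batches and was lower in batch 2 (-9.95, edgeR adjusted p = 0.0327).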

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

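The thinning of the libraries and the test of dilution on the identity list were chosen only after the results had been seen, and the marker genes used in the tests of other cell types were listed after part of the data had been seen. Bootstrap intervals come from 10000 resamplings of the genes of a list. They do not measure the spread between libraries, and genes of the same libraries are not independent.

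Insulin was lower and somatostatin, Ppy and Pyy were higher in all 4 bottom libraries than in any top library. Alpha cell markers other than Gcg had a median log2 fold change of -0.34 (8 genes, 95% bootstrap interval -0.67 to 0.31, so more alpha cells cannot be told from fewer). Delta cell markers other than Sst had one of 3.39 (4 genes, 0.52 to 5.47). These values argue against a lower share of beta cells that raised every other islet cell type alike. Delta and PP cells among the bottom cells stay open as a candidate explanation. Of the 8 listed markers, 5 stand in the delta cell list and 3 in the PP and epsilon cell list. Those 3 did not pass the low-count filter, so PP cells have no support here beyond Ppy and Pyy. The cells were sorted as beta cells, but Gcg made up 5.29% to 11.8% of counts in top libraries. How far the sort removed other islet cells is therefore not known here. Dilution of beta cell RNA by cells that express none of the identity genes is argued against as the whole cause of the insulin difference, for these genes as a list. The 22 tested identity genes other than insulin had a median 2.12 above it (1.13 to 2.57, over genes and not libraries). Iapp does not decide this. It stood at 0.958%, 1.02%, 3.16% and 2.48% in bottom 1 to bottom 4 and at 2.47% to 3.11% in top, so both bottom libraries lay below all top ones only in batch 1. Dilution by cells that share part of the identity genes stays open. The 9 other beta cell genes, from -4.51 to -1.36, had a median of -2.83 against -2.88 for insulin, a difference of 0.05 (-1.40 to 1.13). A difference between the sorted populations themselves, in which bottom beta cells may express somatostatin, Ppy and Pyy, was not tested.

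MHC class II genes summed to 1780 CPM in top 3, far from the next top library at 170 CPM. The same library stood apart in H2-Aa (671 CPM, next 61.5), H2-Ab1 (306, next 32.9), H2-D1 (1500, next 481), Cd274 (223, next 40.9) and the interferon response sum (9430, next 1860). Leukocytes in the bottom libraries could raise MHC class II, and cannot be told apart from an effect within beta cells, since pan-leukocyte markers had a median log2 fold change of 1.36 with an interval of -0.13 to 2.55 (12 genes, no low-count filter). In top 3 pan-leukocyte markers summed to 11.1 CPM, within the 5.42 to 11.4 CPM of the other top libraries, so no higher level of these markers went with MHC class II there. The difference between the sorted populations that the design names stays open and was not tested.

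Intestinal transcripts were high in bottom 1 and bottom 2, with Fabp2, an intestinal fatty acid binding protein, at 7929 and 1780 CPM and Apoa1, an apolipoprotein made in intestine and liver, at 7125 and 1591 CPM, and summed intestinal genes at 26310 and 6137 CPM against 63.9 to 1674 CPM in top. Both pointed up in batch 1 (log2 difference 4.26 for Fabp2 and 4.09 for Apoa1) and down in batch 2 (-6.07 and -5.14), a contrast that did not pass in the interaction test (edgeR adjusted p = 0.499 for each). The fall in batch 2 rests on top 4, at 278 CPM of Fabp2 and 75.3 CPM of Apoa1. Top 3 stood at 2.35 and 1.24 CPM, and bottom 3 and bottom 4 at no more than 1.79 and 0.63 CPM. Over both batches the sign of each gene turned without top 4, bottom 3 or bottom 4. A batch difference of equal size in all libraries is argued against only for intestinal genes measurable in top. The 23 genes of at least 1 CPM on average had a median log2 ratio of batch 1 to batch 2 of 1.31 in top libraries and 7.38 (6.68 to 9.28) in bottom libraries. With 0.5 CPM added, genes near 0 in top give ratios near 0 there, so these medians alone cannot decide. The log2 ratios in top and bottom were 0.85 and 11.18 for Fabp2, 1.31 and 10.04 for Lgals4, 2.73 and 11.96 for Apoa1, and 5.65 and 9.75 for Sis. Only Mep1a had the higher ratio in top. Intestinal epithelial cells in bottom 1 and bottom 2 remain a candidate source. A sort for beta cells is meant to remove them, but how far it did so is not known here. Acinar genes were high there too, at 16710 and 5592 CPM, and stood at 146 to 911 CPM in top. No biological explanation was tested, as the design gives none for this pair of libraries.

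The 52 genes that differed between populations exceeded every other split of the libraries. Only 1 of the 35 splits into 4 and 4, the real one, gave as many, and the highest other gave 0. That share is under 0.05 only if the batches are ignored and the libraries are taken as independent, so chance is not excluded. Each other split mixes top and bottom libraries, so a difference between the populations adds to the spread within its parts. Its count of 0 therefore does not measure how many genes chance gives. The 18 splits with 2 batch 1 libraries in each part, where the highest other also gave 0 against 52, are too few for a share under 0.05. Depth is argued against as their cause, since 58 genes passed after every library was thinned to the smallest total.

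The other libraries that stood apart within their population are given as values. The rule used sets apart about 1 in 20 groups of independent, normally distributed values, and 26 of 144 groups were set apart. These groups come from the same libraries and need not be normally distributed, so the number does not measure an excess over chance. Bottom 2 held the highest glucagon share at 13.1% (next 5.11%) and the highest levels of Acot7 (164 CPM, next 66.4), Car15 (26.6, next 11.7) and Ucn3 (151, next 28.4). Bottom 3 was highest in Cd24a (1020 CPM, next 567), Hhex (474, next 156) and Ptprc (2.95, next 0.280). Bottom 4 was highest in Col3a1 (187 CPM, next 25.9), in Sparc, a matrix protein of stromal cells (408, next 65.9), and in T2 (3.87, next 0.898). Bottom 1 was highest in Rac2 (21.1 CPM, next 5.29). Top 1 was highest in Apoa1 (483 CPM, next 75.3) and Slc7a7 (2.47, next 0.126). Top 2 was highest in Chga (2520 CPM, next 1820), Mki67 (10.3, next 1.44) and C3 (15.7, next 1.01). Top 3 held the highest somatostatin share of the top libraries at 0.44% (next 0.246%). Top 4 was lowest in Kcnj12 (6.07 CPM, next 14.6) and held the single count of Col3a1 and that of Sparc in top (0.159 CPM each, next 0).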

How the results depend on the processing

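Thinning, a robust prior, and the omission of bottom 1 and top 3 together were chosen only after the results were seen. All 52 genes kept their direction wherever they were tested, and the median of all genes never shifted by over 0.1. RLE scaling called 31 genes higher and 17 lower, upper-quartile scaling 32 and 24, TMM without abundant genes 33 and 19, thinning 34 and 24, the robust prior 34 and 23, and the omission of bottom 1 and top 3 together 46 and 26, with 36 of the 52 shared. Without a low-count filter 136 were higher and 68 lower among 17392 tested, all of at least 2-fold, and with 5 CPM in 4 libraries 39 and 29. DESeq2 called 368 and 219 (362 and 213 by 2-fold), limma-voom 26 and 31 (24 and 30), and limma-trend 78 and 59 (77 and 58), and the cause was not tested. Without the batch term 18 were higher and 14 lower. Batch 1 alone gave 2 and 0 in edgeR (1360 genes at an unadjusted p under 0.05) and batch 2 alone 2 and 0 (1231), with fewer libraries. Leaving out 1 library gave 3 (top 2) to 36 (bottom 1) genes higher and 5 (top 2) to 24 (bottom 1) lower, by 2-fold too. The title numbers were not taken to pair the libraries. The correlations for number 1 (r 0.087 and 0 in batches 1 and 2) each rest on 1 difference between 2 libraries per population, so they cannot settle whether the title numbers do. A replicate block made of the batch and these numbers left 0 genes higher and 0 lower in edgeR (710 at an unadjusted p) and 15 of the 23 called lists. Only the libraries numbered 1 compare the populations within a block, so few libraries carry that test. Of the 23, 7 were called with an estimated correlation and 17 in every omission. Fry called 13 lists, 12 of the 23 and the T cell list. The interaction with batch gave 71 genes without the filter, and 0 with RLE scaling and in every omission.

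The insulin difference of -28.19 percentage points and that of the 100 most abundant genes of -14.75 had an exact p of 0.0556 within batches, the smallest possible, and the latter ranged from -17.28 to -12.92 over the omissions. Among 58 tested genes of the text, 937 of 1320 alternative values kept direction and side of the threshold, 305 lost the call, 56 gained it and 22 turned sign, the cause of which was not tested. Apoa1 had log2 fold changes of 4.70 in limma-voom, 3.89 without the batch term, 4.06 in batch 1, 2.04 with the replicate block and 0.58 in limma-trend, and -3.995 to 2.54 over the omissions, against -0.56. Fabp2 had 4.46, 3.63, 4.23, 2.13 and 0.42, and -4.71 to 2.67, against -0.92. Cd274 had -0.41 in batch 2, -0.28 with the block and -0.007 to 1.26 over the omissions. Gcg had 0.48 in batch 1, and Pdx1 0.73 with the block and -0.61 to 0.35 over the omissions. Among list tests 604 alternatives were the same, 60 lost the call, 19 gained it and 8 turned. In batch 2 alone glycolysis (adjusted p = 0.942), oxidative phosphorylation (0.0448) and antioxidant genes (0.544) turned lower. Without bottom 1 and top 3 oxidative phosphorylation (0.916) and Schwann cell genes (0.907) turned lower. Over the omissions these 2 had adjusted p of 0.00447 to 0.731 and 0.478 to 0.905. Simulated changes of 1 on the log2 scale were recovered in 0% of 66 genes by the edgeR test, so the absence of a call does not show the absence of such a difference.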

Other observations

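The marker genes of the test of stromal cells were listed after part of the data had been seen.

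Bottom libraries differed among themselves in transcripts that the comparison of populations does not describe. Endothelial genes summed to 11, 25.4, 101 and 542 CPM in bottom 1 to bottom 4 and to at most 9.21 CPM in top. B cell genes summed to 2.70 to 20.1 CPM in bottom and 6.84 to 18.6 CPM in top. The complement gene C3 stood at 8.96, 209, 452 and 747 CPM in bottom 1 to bottom 4. Cyp2b10 stood at 325 and 124 CPM in bottom 1 and bottom 2 and at 0.11 and 0.09 CPM in bottom 3 and bottom 4, as intestinal transcripts were also high in the former. In a principal component analysis the component with the most variance (29.4%) placed bottom 1 at 174.5 and bottom 2 at 72.8, and the other 6 libraries between -82.7 and -10.8. The next component (17.7%) placed bottom 3 at -97.4, bottom 4 at -82.4 and bottom 2 at -46.9, while the 4 top libraries and bottom 1 lay between 32.5 and 62.5.

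Fibroblast transcripts were found in bottom libraries together with Ccl19, a chemokine made by stromal cells of lymphoid tissue. Lymphoid stroma or fibroblasts in the bottom sort may be a source of these. Other genes of such cells were higher in bottom by a median log2 ratio of 4 (12 genes, 95% bootstrap interval over genes 2.91 to 5.25). Only genes of at least 1 CPM on average were kept, and most of them were near 0 in top. Such genes could pass only through bottom, so the filter favoured a positive median and the ratio does not decide on a source. Sparc, among the most abundant of them, stood at 0.1, 53.8, 65.9 and 408 CPM in bottom 1 to bottom 4, with 1 count in top and 5607 in bottom, a ratio of 4090 with a counting interval of 734 to 162000. Several of these genes also stand in the stellate cell and fibroblast list, so the test is not independent of it. A sort for beta cells is meant to remove such cells, but how far it did so is not known here. Whether beta cells of the bottom population expressed any of these genes was not tested.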
